A study of Mus musculus with 6 samples.

How the data were processed

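DNA methylation was measured by reduced representation bisulfite sequencing, in which genomic DNA is cut at CCGG sites by the enzyme MspI and short fragments, rich in CpG dinucleotides, are converted with bisulfite and sequenced. The samples were the right testes of 6 adult male mice of the outbred KM strain. The left testis had been removed before puberty in 3 of them (hemicastrated), and the other 3 had sham surgery. Each mouse gave 1 library, and no pooling was stated. Per the labels' protocols, size-selected fragments were converted with a Zymo EZ DNA Methylation-Gold kit, amplified by PCR and sequenced on an Illumina GAII in paired-end mode. Per the submitters' processing notes, Bismark (its version is not given in the sources used here), TopHat2 2.0.11 and the mouse build GRCm38 were used, with no role stated for each. Trimming, removal of duplicate reads and coverage filters are not given in the sources used here.

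The authors deposited, for each library, a list of cytosine positions with 2 read counts, the methylated and the unmethylated count, and the methylation level in percent. The deposited counts are raw counts with no normalization, and the deposited percent equals the methylated count over the sum of both counts at every position. The files name neither strand nor sequence context. Of all positions listed in any library, 55.2% had another listed position next to them, as the cytosines of the 2 strands of a CpG do, so positions were treated as CpG cytosines, each strand a site. The libraries held between 64504011 and 78630942 calls and listed between 4188334 and 6473931 positions. Of the positions in each library, 49.8% to 54.2% had a single read, while positions with at least 10 reads held 88.7% to 93.3% of the calls. Calls on mitochondrial DNA, which is taken here as nearly unmethylated, were methylated in 0.478% to 0.617% of cases, with Wilson 95% intervals between 0.326% and 0.884%. These intervals cover counting error only, because PCR copies are not independent molecules.

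Sites on chromosomes 1 to 19, X and Y with at least 10 reads in all 6 libraries were kept, which left 952515 sites. A library's mean methylation level was the unweighted mean over these sites, and group means of such values were compared by exact two-sided permutation tests, which cannot give a p below 0.1 with 3 against 3. Differential methylation was tested with edgeR 4.0.16 in R 4.3.3, on methylated and unmethylated counts in one model with a column per library and a term for methylation by group, by the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. Features were single sites, fixed tiles of 500 bp, windows at gene ends and gene bodies, the last 3 with at least 3 sites, whose counts were summed. Features methylated in no read or in every read were left out. The empirical Bayes prior of the single-site fit had infinite degrees of freedom, so that all sites shared 1 spread and a site's own spread between animals did not enter its test.

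Genes came from a RefSeq gene table of the same build, which gives gene boundaries without strand, exons or transcription starts. The promoter planned before the data were examined, 1000 bp either side of the transcription start, was therefore replaced by a window of 1000 bp either side of the gene boundary with more listed positions, termed the CpG-richer gene end. That choice used neither methylation nor group. Of 34616 genes, 32065 had a richer end and 14948 of those ends were measured, with 12954 distinct sets of sites. Among 2178 genes with both ends measured, the richer end was the less methylated one in 71.5%. Some of these windows may lie at the far end of the gene, which cannot be told without the strand. Gene bodies were genes without 1000 bp at each boundary. The planned window from 2000 bp upstream to 500 bp downstream needs the strand and was not run, and 2000 bp either side was used instead.

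Before the data were examined, 15 gene lists were fixed, and all 274 symbols were found in the gene table, 2 of them through synonyms. Lists with at least 5 measured windows were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 ratios of methylated to unmethylated counts, 1 being added to each count. The 2 imprinted lists used windows reaching 5000 bp outside and 1000 bp inside the richer gene end and were compared as 1 mean level per library. The rule for named features took, for sites, the 5 smallest p in each direction among calls. For tiles and gene bodies it took the 3 smallest p in each direction where none passed, and for gene ends 5 in each direction. For each list it took the members past 0.05 when adjusted over the list alone, or otherwise the 2 members with the smallest p. For the 2 imprinted lists it allowed every measured member. Features named outside this rule are described as chosen after their values were seen.

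The model was tested on simulated data made from the real mean levels and coverage, with 200 features shifted in the hemicastrated group. With counting error as the only spread, shifts of 20 points were recovered in 58% of 50 sites and those of 40 points in 88%, and both in 100% of tiles, gene ends and gene bodies. With the real residuals between animals, shifts of 20 points were recovered in 10% of 50 sites, 42% of tiles, 90% of gene ends and 56% of gene bodies, and shifts of 40 points in 46%, 78%, 94% and 98%. Smaller shifts were recovered less often, with 0%, 16%, 68% and 24% at 5 points and 0%, 20%, 78% and 36% at 10 points in the same order. In that simulation 135 of the 952515 sites were called without having been shifted. Recovery was not examined by methylation level. As 83.5% of the measured gene ends lay below 5%, the shares for gene ends need not hold at methylated ones. Alternatives covered coverage minimums of 5 and 20 reads, removal of sites above the 99.9 percentile of coverage, autosomes only, other feature sizes, each library left out in turn, the replicate number as a block, limma, a quasi-binomial model per feature and Fisher's exact test on group sums, which ignores the spread between animals. A robust prior, the removal of sites spanning 40 points or more over the 6 libraries, other gene ends, 2000 bp windows and fry for changes in either direction were added after the data had been seen. Other software was Python 3.11.15 with SciPy 1.17.1, pandas 2.3.3, NumPy 2.4.6, numba 0.67.0 and matplotlib 3.10.9.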

Results

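Reduced representation bisulfite sequencing was used to ask whether removal of the left testis before puberty was accompanied by a different DNA methylation of the right testis at maturity. Libraries from 3 hemicastrated and 3 sham-operated KM mice were compared. The hemicastrated libraries held 72564123, 69245502 and 76619701 methylation calls and the sham libraries 77721211, 78630942 and 64504011. Over the 952515 CpG sites with at least 10 reads in every library, levels of single sites correlated between libraries with Pearson's r of 0.987 to 0.988 within groups and 0.986 to 0.989 between groups, across sites, which are not independent replicates.

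The mean CpG methylation level of the right testis was 29.7% ± 0.238 (SD, n = 3) in hemicastrated and 29.9% ± 0.361 (SD, n = 3) in sham-operated mice. CpG-richer gene ends, where CpG island promoters tend to lie, were nearly unmethylated, at 3.16% ± 0.0797 and 3.16% ± 0.0738 (SD, n = 3 each). Levels were higher inside genes, at 48.5% ± 0.284 against 48.7% ± 0.470, and highest outside genes, at 64.9% ± 0.935 against 65.7% ± 0.946 (SD, n = 3 each). Chromosome X had 41.1% ± 0.517 in hemicastrated and 41.5% ± 0.505 in sham-operated mice (SD, n = 3 each). The difference of the overall means, hemicastrated minus sham, was -0.225 points with a standard error of 0.250, smaller than the spread between animals (exact two-sided permutation test, p = 0.4, the smallest possible being 0.1). It was -1.31 points with sites weighted by coverage, and ran from -0.427 without sham replicate 1 to -0.0797 without sham replicate 2. Over the 11 levels and shares compared in this way, the Benjamini-Hochberg adjusted exact p was 0.611 or higher.

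**Figure D1:**
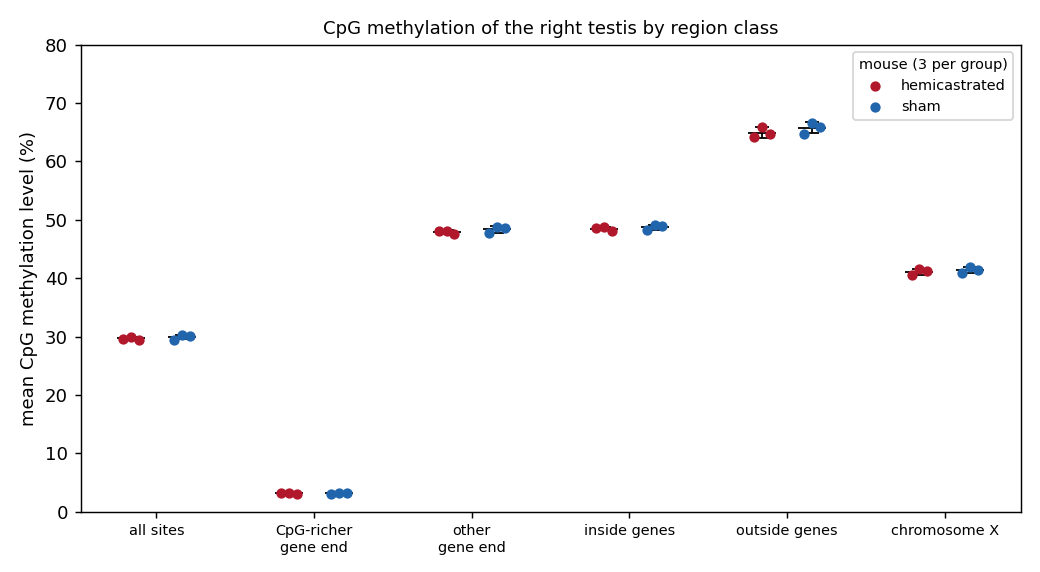
Mean CpG methylation level in percent (vertical axis) of 6 right testes for all sites, 4 classes of region and chromosome X; points are single mice, bars the group mean and SD of 3. CpG-richer gene ends lay near 3.16% in both groups and sites outside genes near 64.9% and 65.7%, with the groups overlapping in every class shown.

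The named single CpG sites lay inside 5 genes and in intergenic DNA. Inside Il4ra, which encodes the alpha chain of the interleukin 4 receptor, the neighbouring positions 125572102 and 125572103 of chromosome 7 were methylated at 81.6% ± 26.2 and 76.5% ± 31.5 in hemicastrated mice and at 1.02% ± 0.882 and 0% in sham-operated mice (SD, n = 3 each). Inside Il9r, the interleukin 9 receptor gene, position 32190953 of chromosome 11 was at 0.240% ± 0.415 in hemicastrated and 48.1% ± 2.69 in sham-operated mice. Inside Enox1, which encodes an oxidase of the cell surface, position 77591007 of chromosome 14 was at 15.8% ± 27.3 against 96.7% ± 1.01. In all, edgeR's quasi-likelihood test called 706 of 814966 tested sites, 367 higher and 339 lower in hemicastrated mice. An unadjusted p below 0.05 was found for 21320 sites (2.62%), fewer than the share of 0.05 that evenly spread p values would give.

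The other named sites with higher levels in hemicastrated mice were position 24492549 of chromosome 13, 8974 bp from Ripor2 (63.9% ± 55.3 against 0.153% ± 0.265), position 125293119 of chromosome 7, outside genes (81.9% ± 24.3 against 0.725% ± 1.26), and position 127490429 of chromosome 5, inside Tmem132c (47.6% ± 47.9 against 0%). The other named sites with lower levels were position 47902783 of chromosome 4, outside genes (0% against 80.7% ± 27.8), position 76735705 of chromosome 14, outside genes (12.1% ± 19.3 against 88.4% ± 10.4), and position 86081946 of chromosome 15, inside Gramd4 (0% against 51.1% ± 47.9). The lowest coverage of these 10 sites was 24 reads in a library, at Enox1, and their adjusted p by edgeR ran from 8.02e-33 to 1.44e-15. A site's own spread between animals did not enter these p values. The named sites need not be independent. The 2 positions in Il4ra were taken as the 2 strands of 1 CpG. In hemicastrated replicates 1 to 3, position 125293119 of chromosome 7 had 94.4%, 53.95% and 97.4% and position 125572103 had 96.3%, 40.1% and 93.0%. At 3 of the 10 the levels within a group ran from under 1% to over 94%, so that the difference rested on 2 of the 3 mice: at chromosome 13 hemicastrated replicate 3 had 0%, at Tmem132c hemicastrated replicate 1 had 0.76%, and at Gramd4 sham replicate 3 had 0%. Without hemicastrated replicate 3 the difference at chromosome 13 went from 63.7 to 95.7 points and at Tmem132c from 47.6 to 23.1, and at Gramd4 it went from -51.1 to -29.2 without sham replicate 2 and to -76.7 without sham replicate 3. Of the 706 called sites, 258 (36.5%) had groups that did not overlap, where chance gives 10% of unselected sites. The called sites were selected for a group difference, so that 10% is no baseline for them. The number of calls differed between models: a quasi-binomial model with each site's own dispersion called 0 sites, limma 147 and edgeR with a robust prior 446. The quasi-binomial model takes a site's spread from the 6 libraries alone. Over 814966 tested sites it could hardly reach the adjusted threshold, so its 0 is no test of the calls. The main edgeR test on other groupings of the 6 libraries into 3 and 3 called 666 to 1165 sites, against 706 for the real one. When sites spanning 40 points or more over the 6 libraries were left out, 46 sites were called. A site with a large difference between the groups spans widely by construction, as 648 of the 706 called sites did, so this removal is no test of the calls.

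**Figure D2:**
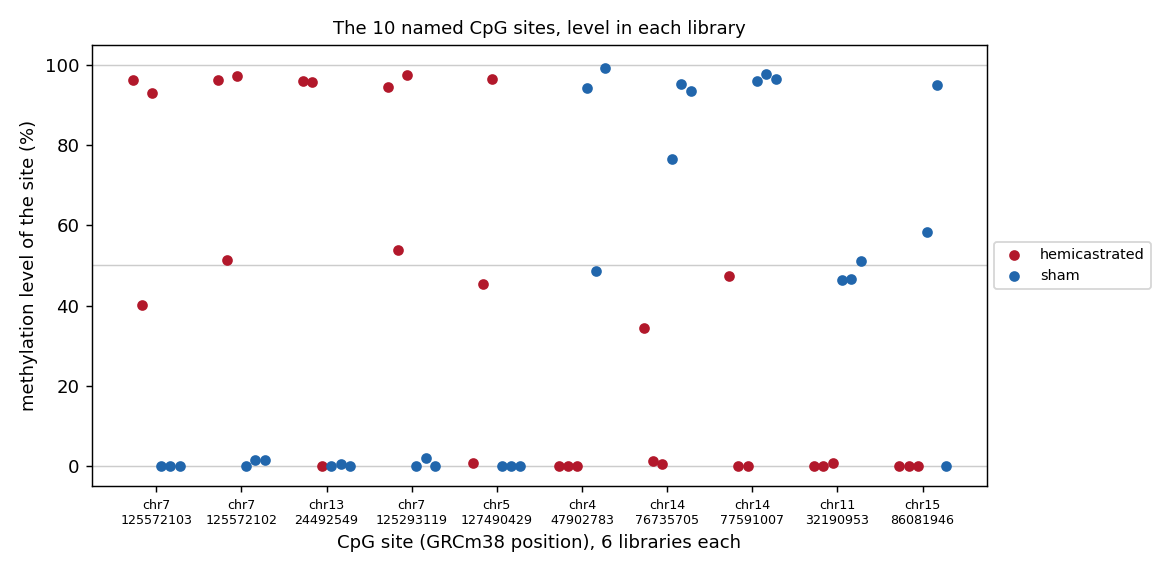
Methylation level in percent (vertical axis) of the 10 named CpG sites in each of the 6 libraries; each point is 1 mouse, red hemicastrated and blue sham, and grey lines mark 0, 50 and 100%. At Il9r (chromosome 11) the 3 sham mice sat between 46.4% and 51.2% and the hemicastrated mice at 0.72% or below.

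Among 500 bp tiles with lower levels in hemicastrated mice, the smallest p was that of an intergenic tile of chromosome 6, from 51788001 to 51788500 and 70664 bp from Skap2, an adaptor of Src kinases. Its level was 65.6% ± 5.39 in hemicastrated and 95.8% ± 1.23 in sham-operated mice (SD, n = 3 each; edgeR adjusted p = 0.0998), and it did not pass the threshold. The tile of chromosome 8 from 40817501 to 40818000, 5008 bp from Adam39, a member of a family of membrane metalloproteases, had 80.1% ± 1.94 against 94.4% ± 0.964. The tile of chromosome 1 from 190901501 to 190902000, inside Rps6kc1, had 71.6% ± 14.1 against 96.5% ± 0.930. On the higher side stood tiles inside Col6a3, a collagen VI chain (chromosome 1, 90833001 to 90833500, 96.1% ± 1.44 against 83.8% ± 0.666), on chromosome 19 from 16018001 to 16018500 (95.7% ± 1.15 against 84.9% ± 0.399), and inside Rbms3, which encodes an RNA-binding protein (chromosome 9, 117387501 to 117388000, 95.2% ± 0.593 against 77.6% ± 8.23). No tile of 71149 passed edgeR's test, limma and the quasi-binomial model called 0, and Fisher's exact test on group sums called 6869. An unadjusted p below 0.05 by edgeR was found for 3055 tiles (4.29%, below a share of 0.05). With a robust prior the tile of chromosome 6 was called (adjusted p = 0.0489). The other sites, those spanning less than 40 points, gave differences of 0.735 points at Col6a3, 0.693 at Rbms3 and -0.352 on chromosome 19, and of -14.3 at the tile near Adam39. The removed sites include those with the largest group differences by construction. The differences at Col6a3, Rbms3 and on chromosome 19 thus rested on the removed sites and not on a shift across the tile.

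At CpG-richer gene ends, no gene passed. The largest negative differences among the named windows were at Gm41523, at 11.2% ± 4.54 in hemicastrated and 40.7% ± 17.9 in sham-operated mice, and at a window shared by Zbtb46, a transcription factor of dendritic cells, and Abhd16b, at 62.0% ± 0.980 against 83.4% ± 6.48 (SD, n = 3 each). Alkbh6, of the AlkB dioxygenase family, had 66.5% ± 2.94 against 81.6% ± 2.22, and Gm33620 had 74.9% ± 1.62 against 89.2% ± 4.57. The named windows with higher levels in hemicastrated mice were all nearly unmethylated, and in sham-operated mice lay below the 0.478% to 0.617% of methylated calls on mitochondrial DNA. They belonged to Pigm, a mannosyltransferase of GPI anchor synthesis (2.03% ± 1.43 against 0.374% ± 0.0611), Eda, the ligand ectodysplasin (1.04% ± 0.594 against 0.166% ± 0.114), Crim1, a transmembrane protein that binds bone morphogenetic proteins (0.776% ± 0.103 against 0.299% ± 0.0684), Ttc21b, a protein of intraflagellar transport (0.762% ± 0.298 against 0.170% ± 0.0981), and Ddi2, a protease (1.05% ± 0.461 against 0.336% ± 0.0646). The smallest adjusted p by edgeR was 0.482 over 14927 tested windows. An unadjusted p below 0.05 was found for 661 windows (4.43%, below a share of 0.05). The limma and quasi-binomial models called 0, and Fisher's exact test on group sums called 835. Without hemicastrated replicate 3 Pigm was called (edgeR adjusted p = 0.000158). Without sham replicate 3 1700049E22Rik was called (11.5% against 61.0%, adjusted p = 0.00264, named after its value was seen). With the replicate number as a block, edgeR called Pigm and Gm41523 (adjusted p = 0.0183 each) and the window of Zbtb46 and Abhd16b (0.0287) among 6 ends, although the numbers were not taken as pairs. Without hemicastrated replicate 1 the difference at Pigm was 1.07 points, and without hemicastrated replicate 2 that at Ddi2 was 0.451. Over sites spanning less than 40 points the difference at Gm33620 was -7.36 points instead of -14.2.

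In gene bodies, Slc25a51, the mitochondrial NAD carrier, had 69.1% ± 3.70 in hemicastrated and 85.6% ± 1.35 in sham-operated mice (SD, n = 3 each) over 58 sites of chromosome 4 between 45396924 and 45407916. Il9r had 43.1% ± 1.19 against 66.7% ± 1.25 over 6 sites, and Irak1bp1, which encodes a binding partner of an interleukin 1 receptor kinase, 48.3% ± 0.616 against 75.3% ± 1.77 over 4 sites. Higher levels in hemicastrated mice stood at Adck1, a mitochondrial protein of the ADCK kinase family (96.1% ± 0.267 against 86.5% ± 0.544, 9 sites), Gm33539 (94.7% ± 0.787 against 83.4% ± 6.41, 4 sites) and Il4ra (92.8% ± 3.22 against 84.3% ± 1.22, 29 sites). None of 12621 gene bodies passed, with edgeR adjusted p of 0.0917 for Adck1 and 0.102 for Slc25a51, Il9r and Irak1bp1. An unadjusted p below 0.05 was found for 431 bodies (3.41%, below a share of 0.05). The limma and quasi-binomial models called 0, and Fisher's exact test on group sums called 2485. Over sites spanning less than 40 points, a removal that takes out large group differences by construction, the difference was 0.448 points at Adck1, -0.263 at Il4ra, -13.2 at Il9r and -16.5 at Slc25a51. The differences at Adck1 and Il4ra thus rested on the removed sites and not on a shift across the gene body. In Il4ra the removed sites include the 2 named positions, taken as the 2 strands of 1 CpG. Without sham replicate 2, Ibsp was called (96.3% against 81.7%, adjusted p = 0.0297; named after its value was seen).

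Genes of sperm formation were compared as fixed lists. In these and the following lists, nearly unmethylated members lay near or below the 0.478% to 0.617% of methylated calls on mitochondrial DNA. Their differences sit at the floor of the measurement, and the log ratios tested with camera and fry include them. The spermiogenesis list, which holds genes of sperm head and tail assembly, had a mean level of 17.4% ± 0.189 in hemicastrated and 16.5% ± 0.159 in sham-operated mice (SD, n = 3 each). Its mean difference of 0.852 points was 0.253 without Tnp1, and its median difference was 0.134. Of its 19 measured members 14 had a higher and 5 a lower group mean in hemicastrated mice, and none passed edgeR's test over all genes or adjusted over the list alone. Its members with the smallest p were Catsper2, a subunit of the sperm calcium channel (0.701% ± 0.107 against 0.382% ± 0.0694), and Tnp1, a transition protein of spermatid chromatin (23.5% ± 4.29 against 11.9% ± 3.23, 5 sites). The camera p was 0.0221 and its adjusted value over 10 lists 0.164, with adjusted p = 0.583 with an estimated correlation, and fry gave an adjusted p of 0.0764, so the list was not called. The meiosis list had 10.5% ± 1.36 against 10.4% ± 0.394 with 9 members higher and 13 lower (camera adjusted p = 0.543). Its mean was higher in hemicastrated mice, while its median difference of -0.118 points and the camera test pointed lower, and its mean difference went from 0.186 to -0.568 points without hemicastrated replicate 1. Its members with the smallest p were Mei4, needed for meiotic double-strand breaks (0.318% ± 0.0539 against 0.829% ± 0.401), and Sycp2, of the synaptonemal complex (16.04% ± 3.17 against 11.2% ± 2.77). The difference at Mei4 was -0.282 points without sham replicate 3, and that at Sycp2 was 2.95 with at least 20 reads per site.

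The spermatogonial list had 2.64% ± 0.296 in hemicastrated and 2.25% ± 0.127 in sham-operated mice, with 13 of 18 members higher and 0 past the test. Its mean difference of 0.394 points was 0.0378 without Pou5f1, measured over 4 sites, and its median difference was 0.0759. Bcl6b, a regulator of stem cell renewal, had 0.286% ± 0.164 against 0.777% ± 0.438, and Pou5f1, the pluripotency factor Oct4, 19.4% ± 4.82 against 13.0% ± 3.22. Their differences were -0.263 points without sham replicate 2 and 4.04 without hemicastrated replicate 2. The germline genes whose promoters are methylated in somatic cells had 17.3% ± 2.95 against 15.5% ± 1.504 (SD, n = 3 each), with 11 of 15 members higher, and hemicastrated replicate 1 stood at 20.7% against 13.8% to 16.6% in the other libraries. Without that library the difference of the list means went from 1.80 to 0.1001 points. Sycp3, a core protein of meiotic chromosome axes, had 19.8% ± 6.39 against 13.6% ± 4.75 and Zfp42 had 15.9% ± 7.30 against 10.1% ± 1.51. Without hemicastrated replicate 1 their differences went from 6.27 to 2.92 and from 5.82 to 2.13 points, and without sham replicate 2 that of Sycp3 was 3.72 and without hemicastrated replicate 2 that of Zfp42 was 9.44. The piRNA list had 10.4% ± 2.20 against 9.37% ± 0.734, with 4 of 7 members higher. Its members Tdrd5 (0.342% ± 0.119 against 0.669% ± 0.116) and Exd1 (0.594% ± 0.181 against 0.325% ± 0.0568) went opposite ways and did not pass when adjusted over the list alone. Tested with fry for changes in either direction, chosen after the data had been seen, this list was called (adjusted p = 0.0492), and it passed in 3 of the 6 fits with a library left out (adjusted p from 0.0370 to 0.573). With the replicate number as a block, the same fry test did not call it (adjusted p = 0.211). The camera adjusted p of the spermatogonial, germline and piRNA lists were 0.774, 0.543 and 0.834. For the piRNA list the camera test pointed lower, while the mean and the median difference of 0.270 points were higher in hemicastrated mice. Without hemicastrated replicate 1 its mean difference went from 0.987 to -0.250 points.

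The lists of Leydig cells, Sertoli cells, hormone signalling, the cell cycle and the methylation machinery differed by less than 1 point between the groups. Of their measured members 8 of 14, 16 of 17, 12 of 13, 14 of 14 and 5 of 5 were below 5%, in that order. The Leydig cell and steroidogenesis list had 23.7% ± 0.144 in hemicastrated and 24.3% ± 1.17 in sham-operated mice, with Srd5a1, a steroid reductase (0.745% ± 0.321 against 0.527% ± 0.0851), and Fdx1, an electron carrier of steroid synthesis (0.552% ± 0.0747 against 0.416% ± 0.119), as the members with the smallest p. The Sertoli cell list had 6.09% ± 0.171 against 5.87% ± 0.115, with 12 of 17 members higher and Inhbb, an inhibin subunit (0.642% ± 0.0980 against 0.459% ± 0.135), and Clu, the secreted chaperone clusterin (0.974% ± 0.386 against 0.511% ± 0.0912), named by the rule. Hormone and growth factor receptors and ligands had 1.06% ± 0.383 against 0.890% ± 0.103, with Dio3, which inactivates thyroid hormone, at 0.620% ± 0.213 against 0.407% ± 0.0681 and the estrogen receptor gene Esr2 at 0.640% ± 0.210 against 0.390% ± 0.0957. Cell cycle genes had 0.674% ± 0.0706 against 0.495% ± 0.0868 (exact permutation p = 0.1, the smallest possible, and 0.5 when adjusted over 15 lists). Among them Myc stood at 0.795% ± 0.447 against 0.296% ± 0.0364 and Cdk4 at 0.903% ± 0.334 against 0.393% ± 0.223. Genes of the DNA methylation machinery had 0.494% ± 0.111 against 0.495% ± 0.143, among them Tet3 at 0.467% ± 0.0886 against 0.594% ± 0.170 and Uhrf1 at 0.550% ± 0.197 against 0.451% ± 0.258, with a median difference of 0.0242 points against a mean difference of -0.000955. Without hemicastrated replicate 1 the difference of the hormone list means went from 0.169 to -0.0358 points, and without sham replicate 3 that of the Leydig list went from -0.533 to 0.130. That of the methylation machinery took either sign, depending on the library left out. Of the named members' differences, 9 moved by over 1.5 times with 1 library left out and kept their sign, while that at Uhrf1 turned, from 0.0992 to -0.0332 points without sham replicate 1. Without hemicastrated replicate 1 Srd5a1 went from 0.218 to 0.0328 points, Clu to 0.294 and Esr2 to 0.131, and without hemicastrated replicate 2 Myc went to 0.756 and Cdk4 to 0.318. Dio3 went to 0.0937 without hemicastrated replicate 3, Fdx1 to 0.0732 without sham replicate 1, and Inhbb to 0.118 and Tet3 to -0.0443 without sham replicate 2. The camera adjusted p of these 5 lists were 0.774, 0.164, 0.543, 0.164 and 0.820 in the order given, so 0 of the 10 lists tested with camera were called, 0 with an estimated correlation and 0 with fry for a shift in 1 direction, while 3 had an unadjusted camera p below 0.05. Over all 15 lists, the Benjamini-Hochberg adjusted exact p of the list means was 0.5 or higher.

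Markers of other testicular cells were measured for few genes and were not tested with camera. The peritubular myoid list had 4.65% ± 1.30 in hemicastrated and 7.55% ± 1.71 in sham-operated mice (SD, n = 3 each; exact permutation p = 0.1, the smallest possible), with 2 of 4 members higher and 2 lower. Tagln, an actin-binding protein of smooth muscle, had 10.8% ± 1.99 against 22.9% ± 7.01 over 8 sites. Without Tagln the difference of the list means went from -2.90 to 0.183 points. Tagln was the 1 list member that passed when adjusted over the list alone (edgeR adjusted p = 0.0175), and it did not pass over all genes (adjusted p = 0.997). The macrophage list had 50.004% ± 0.532 against 50.03% ± 2.13 over C1qa (6.44% ± 1.03 against 6.53% ± 1.60) and Adgre1 (93.6% ± 2.06 against 93.5% ± 4.06). The endothelial list had 0.645% ± 0.0220 against 0.621% ± 0.0604 over Cldn5 (0.803% ± 0.0766 against 0.728% ± 0.0251) and Flt1 (0.487% ± 0.0334 against 0.513% ± 0.104). The differences of the macrophage list and at C1qa, Adgre1 and Flt1 took either sign, depending on the library left out.

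Imprinted regions carrying methylation on the maternal copy had a mean level of 11.2% ± 1.12 in hemicastrated and 10.3% ± 1.12 in sham-operated mice (SD, n = 3 each; exact permutation p = 0.3). Of the 13 measured regions 9 were higher and 4 lower in hemicastrated mice. The differences were largest at Peg10, at 10.7% ± 4.42 against 6.81% ± 1.67, Zrsr1, at 12.3% ± 3.03 against 9.12% ± 1.19, Mcts2, at 11.4% ± 2.90 against 8.34% ± 0.970, and Peg13, at 13.3% ± 0.754 against 10.8% ± 1.89 over 4 sites (exact permutation p of 0.3, 0.3, 0.2 and 0.2). Gnasas1 had 9.64% ± 1.88 against 11.1% ± 2.28, Kcnq1ot1 7.63% ± 5.36 against 9.06% ± 1.77 and Nap1l5 10.7% ± 1.78 against 10.6% ± 3.28. Airn had 10.5% ± 1.02 against 9.88% ± 1.13, Plagl1, a growth regulator, 8.99% ± 2.76 against 8.33% ± 2.41, and Slc38a4, an amino acid transporter, 13.6% ± 0.377 against 14.7% ± 1.87. Nnat stood highest, at 34.7% ± 6.02 against 33.9% ± 0.940, and Grb10 (1.05% ± 0.151 against 0.835% ± 0.127) and Inpp5f (0.417% ± 0.211 against 0.447% ± 0.0650) were nearly unmethylated over the windows measured. The paternally methylated list had 18.0% ± 1.36 against 20.5% ± 2.47 over 4 regions (exact permutation p = 0.2). Within it the noncoding RNA gene Meg3 had 9.25% ± 2.59 against 19.3% ± 4.72 over 7 sites (exact permutation p = 0.1), Dlk1 42.6% ± 3.19 against 46.0% ± 8.66, Zdbf2 18.9% ± 8.65 against 16.1% ± 2.62 and Rasgrf1 1.14% ± 0.890 against 0.494% ± 0.213. Without Meg3 the difference of the paternal means went from -2.51 to 0.00849 points. With 1 library left out 15 of the 17 differences moved by over 1.5 times, and 7 of these took the other sign, among them Dlk1 (from -3.44 to 1.26 points without sham replicate 2) and Zdbf2 (from 2.82 to -2.12 without hemicastrated replicate 1). The difference of the maternal means went from 0.857 to 0.360 points without hemicastrated replicate 1. The windows reached 5000 bp outside the gene end and need not cover the imprinting control region of each gene.

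**Figure D3:**
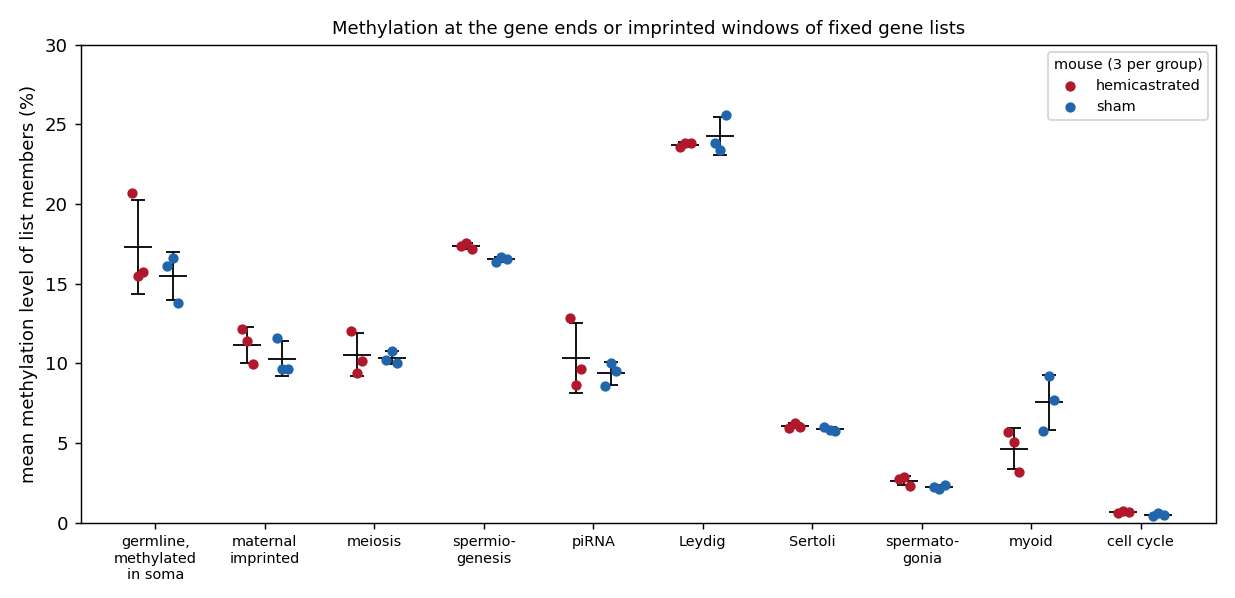
Mean methylation level in percent (vertical axis) of the members of 10 fixed gene lists in 6 right testes; points are single mice, bars the group mean and SD of 3. Spermiogenesis genes lay at 17.4% in hemicastrated and 16.5% in sham mice, and peritubular myoid genes at 4.65% and 7.55%.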

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

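The robust prior, the removal of sites spanning 40 points or more, the other gene ends, the 2000 bp windows and fry for changes in either direction were chosen after the data had been seen. The difference in mean methylation level stayed negative in every alternative run, from -0.427 to -0.0797 points with 1 library left out and at -1.31 with sites weighted by coverage. The count of CpG sites (706) fell to 46 without sites spanning 40 points, to 446 with a robust prior, to 147 with limma (53 higher, 94 lower) and to 0 with the quasi-binomial model, and rose to 5221 with Fisher's exact test (1585 higher, 3636 lower); with 1 library left out it ran from 574 to 728. Tiles (0) became 1 with a robust prior, 3 with at least 1 site per tile (the tile of chromosome 6 and those starting at 88424001 on chromosome 12 and 49911001 on chromosome 14) and 6869 with Fisher's test. Gene ends (0) became 1 with windows of 2000 bp (Gm52115), 0 to 1 with a library left out and 835 with Fisher's test. Gene bodies (0) became 0 to 1 with a library left out and 2485 with Fisher's test. Fisher's test takes reads as replicates, and leaving out wide-spanning sites removes them from the test. With a site's spread taken from 6 libraries alone, the quasi-binomial model could hardly reach the adjusted threshold at single sites. The added tiles of chromosomes 12 and 14 held 1 and 2 sites, below the minimum of 3 in the main test. The called position in Enox1 lay 1983 bp from the nearest boundary of Gm52115. The cause of the other changes was not tested. Gene lists (0) became 1 with fry for changes in either direction, the piRNA list (adjusted p = 0.0492), which passed in 3 of 6 fits with a library left out (0.0370 to 0.573); of the 9 other splits of the libraries 1 called lists in that test, 2 of them. Gene lists stayed at 0 in the other alternatives, of which the other gene end measured 2 lists. The window from 2000 bp upstream to 500 bp downstream was not run, as it needs the strand.

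With the replicate number as a replicate block, gene ends became 6 (Pigm, Gm41523, Zbtb46 and Abhd16b in 1 window, Gm36254 and 1700055K11Rik in another) and sites 643, and the piRNA list was not called by fry for changes in either direction (adjusted p = 0.211), with no other call changed among the counts. The numbers were not taken as pairs: the deviations of same-numbered libraries from their group means correlated at 0.0586, 0.0778 and 0.0346 over tiles. Each library did correlate best with its own number, a hint from the data and not from the design.

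Directions turned for values that had not passed any test. Without wide-spanning sites, a removal that takes out large group differences by construction, the tile of chromosome 19 went to -0.352 and the Il4ra body to -0.263 points. With 1 library left out, Uhrf1 ran from -0.0332 to 0.225, C1qa from -0.566 to 0.845, Adgre1 from -1.95 to 2.11 and Flt1 from -0.0688 to 0.0317 points. Of the other values of named features, 540 kept direction and side of the threshold and 5 passed it. The difference moved by over 1.5 times or turned at 24 of 57 named features with some library left out and at 7 with another coverage minimum. Of the 15 list means, 11 differences moved that far with some library left out and 6 turned.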

Other observations

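The test on levels near allele dosages, the use of the paternal list beside the maternal one, the choice of called sites with moving neighbours and the choice of gene ends below were made after the results had been seen; the tests of neighbouring sites, of other splits and of imprinted regions were set before.

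Some gene ends differed widely between single mice. Of 12103 CpG-richer gene ends with at least 10 sites, 10 spanned 40 points or more over the 6 libraries, whatever the group; as some windows share their sites, these are 7 distinct sets of sites. The sham mean was higher in 6 of the 7, and none passed edgeR's test in the main fit. With the replicate number as a block, the set shared by Gm36254 and 1700055K11Rik passed it (21.1% against 47.8%, adjusted p = 0.0183). At C7, a component of the complement attack complex (chromosome 15, 4986750 to 4988750), the hemicastrated mice had 24.7%, 19.1% and 51.1% and the sham mice 23.8%, 60.8% and 91.8%, and all 12 sites spanned 40 points or more. At Zfp180, a zinc finger gene (chromosome 7, 24080877 to 24082877), the levels were 45.1%, 28.4% and 0.73% in hemicastrated and 0.35%, 32.3% and 0.24% in sham mice, with 11 of 12 sites spanning 40 points. At Dpp7, a dipeptidyl peptidase (chromosome 2, 25355389 to 25357389), they were 46.5%, 42.3% and 7.57% against 27.5%, 53.5% and 56.6%. The window of the noncoding gene AY036118 (chromosome 17, 39847112 to 39849112) ran from 11.9% to 58.7% over 189 sites, with 176158 to 422766 calls per library. Over all tested gene ends the medians were 1712 calls per library and 29 sites. Whether the reads of this window come from 1 locus was not tested, so its levels need not be those of a single gene end.

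The CpG-richer ends of genes for sperm proteins were not all unmethylated, and without the strand it is open whether they hold the promoter. Named after their values were seen, Prm1, the sperm protamine, stood at 87.3% ± 1.71 in hemicastrated and 87.9% ± 4.43 in sham mice, Tssk1, a kinase of spermatids, at 97.1% ± 0.930 against 95.1% ± 1.13, and Catsper1, of the sperm calcium channel, at 94.2% ± 0.839 against 93.1% ± 0.777 (SD, n = 3 each). The Leydig cell genes Star and Cyp17a1, of steroid synthesis, stood at 96.7% ± 1.16 against 97.7% ± 1.55 and 90.01% ± 4.67 against 90.6% ± 2.99. Of 19 spermiogenesis windows 14 were below 5%, as were 8 of 14 in the Leydig cell list.

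For the called CpG sites, sequence variants carried by single mice of this outbred strain are a candidate explanation. A variant at a CpG changes the reads at that CpG, on both strands, and not at its neighbours. Over 622 called sites with another site within 100 bp, the median ratio of the neighbours' difference to the site's own was 0.0153 (95% bootstrap interval 0.0095 to 0.0232). At the 434 called sites where the cytosine on the other strand was measured, it moved along with a median ratio of 0.972. Both strands share the CpG, so this does not separate a variant from a methylation difference of 1 CpG. Levels within 10 points of 0, 50 or 100% were 43.0 points more frequent than at uncalled sites of the same mean level, which decides nothing, since the called sites were selected for wide differences between libraries. A methylation difference limited to 1 CpG would also leave neighbours unmoved and stays open, as does an effect of hemicastration. With 10 splits of the 6 libraries no share under 0.05 can be reached. The real split called 706 sites, and 8 splits, the real one included, called as many or more, up to 1165. The number of calls was thus not above that of arbitrary groupings of these libraries.

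At 53 called sites in 26 tiles the neighbours moved by more than 0.5 of the site's own difference, so a single variant may not account for them, although the median over all called sites was 0.0153. They include 3 sites in Slc25a51, one of which, position 45399646 of chromosome 4, had 71.2% ± 5.26 in hemicastrated and 96.9% ± 1.30 in sham mice, and position 51788387 of chromosome 6, with 51.0% ± 5.35 against 96.5% ± 1.996 (SD, n = 3 each). Groups did not overlap at 26 of the 53, which had been selected for a group difference. Whether these regions follow the surgery or the descent of the mice was not tested.

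For the features without calls the splits decide nothing. The real split called 0 tiles, gene ends, gene bodies and gene lists, which all 10 splits reach by construction, and the highest other split called 2, 7, 0 and 0.

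Whether DNA of male germ cells makes up most of each library could not be told from the imprinted regions. Male germ cells lack the maternal methylation and carry the paternal one, while a somatic tissue has each on 1 of 2 copies. The highest of the 6 library means was 12.2% for the maternal list, below the bound of 25% set beforehand. The paternal list stood at 16.6% to 23.2% over 4 regions, with Rasgrf1 at 1.14% and 0.494%. Germ cell DNA would raise these levels only where the windows cover the control regions, which they need not, so they decide nothing. Windows that miss the control regions could lower or raise the level of either list and stay open as a technical explanation, which was not tested. Germline genes with promoters methylated in somatic cells, which should carry somatic methylation on both copies, had a median member level of 17.8%, against 10.2% for the maternal regions.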
